A study of Mus musculus with 2 samples.

How the data were processed

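Lymph nodes of mice from the AireDTR strain were pooled from the mesentery, neck, groin, armpit and upper limb and from along the aorta, digested enzymatically, and live cells positive for tdTmt and for MHC class II were sorted. The 3′ ends of polyadenylated RNA were then sequenced per cell in droplets on the 10x Chromium platform, version 3 chemistry, per the labels' protocols. The structure of the barcodes leaves that version in doubt. There were 2 libraries, 1 titled DTR negative and 1 titled DTR positive, so each group held 1 library. The labels do not say how many mice were pooled, whether diphtheria toxin was given, or what the tdTmt reporter marks.

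The files used here were, for each library, the deposited list of cell barcodes and the deposited list of features. Neither holds a measured value: the first gives 1 cell barcode per line and the second an identifier, a symbol and a type per row. The matrices of molecule counts that such lists index were not analysed here, so no expression level, depth per cell, cell class or share of cells is given. Cell Ranger 8.0.1, Scanpy 1.10.2 and the build mm10 are named in the submitters' processing notes, without a role for each. The cell-calling settings, the treatment of doublets and the gene annotation are not given in the sources used here.

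The barcodes kept per library were counted with an exact Poisson 95% interval, and their ratio with the exact conditional binomial 95% interval. These intervals cover counting error only, not variation between animals, sorts or loadings, and no test between the groups was made. Barcodes were then split into their first 7 bases, the linker at bases 8 and 9, and their last 7 bases. The pool of possible barcodes was the sum over linkers of first words seen times last words seen. The number of barcodes that both libraries would share by chance was the product of the list lengths divided by that pool. Pairs of barcodes 1 and 2 bases apart were counted within each library and between the libraries. The calculation was tested on simulated libraries of the same sizes. The simulated pool was smaller than the real one and built of random words without a set gap between them. It was recovered to 99.9%. Copying 100 barcodes of 1 simulated list into the other raised the shared count from 58 to 158. That rise follows from the copying itself, so it checks only the counting. Adding 200 simulated split barcodes, each 2 bases from a kept one, to the real lists gave a ratio of close pairs of 1.12 (exact 95% interval 1.05 to 1.21) in the DTR-negative and 1.14 (1.07 to 1.22) in the DTR-positive library.

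Features were matched by Ensembl identifier, without version, to GENCODE release M21, which is built on GRCm38 (the assembly also called mm10). Gene coordinates below are those of M21 on GRCm38, 1-based, and biotypes are those of M21. The order of the matched genes in the feature list was compared with their start on GRCm38 by Spearman's rho across genes, per chromosome and in sliding windows of 51 genes. Genes are not independent replicates, so no p-value was attached. Marker lists for 14 cell classes or functions were fixed before the data were examined, and the named genes are members of those lists, Hbegf and the tdTomato feature. The gfp feature was outside this rule and was named after the list was seen. The members of 1 list are not reported here by name. Genes outside this rule are named only where they mark the ends of a region or overlap a named gene, and were chosen after the comparison was seen. Alternatives were barcodes without their suffix, shared barcodes allowing 1 mismatch, the longer list cut to the length of the shorter, pairs 2 bases apart, symbols matched without regard to case, and features counted by symbol. Python 3.11.15, numpy 2.4.6 and scipy 1.17.1 were used.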

Results

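Cells carrying tdTmt and MHC class II were sorted from pooled lymph nodes of AireDTR mice and profiled by droplet single-cell RNA sequencing. Aire encodes a transcriptional regulator of self-antigen expression, known from thymic epithelium and also expressed by some antigen-presenting cells of lymph nodes. DTR usually denotes the diphtheria toxin receptor, which makes mouse cells sensitive to diphtheria toxin. The design set 1 DTR-negative library beside 1 DTR-positive library, with no replicate of either. The values below describe the cells kept and the genes measurable in these libraries. Molecule counts were not analysed here, so the data below do not say which genes or cell types differed between the libraries.

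The DTR-negative library kept 12859 cell barcodes (exact Poisson 95% interval 12638 to 13083) and the DTR-positive library kept 14906 (14668 to 15147). The DTR-positive library thus held 2047 more, a ratio of 1.16 (exact 95% interval 1.13 to 1.19). These intervals cover counting error only. With 1 library per group there is no replicate spread to set this ratio against, and the number of kept barcodes also depends on how many sorted cells were loaded. No doublets could be called from the lists, and how the authors treated them is not given in the sources used here, so a barcode may stand for more than 1 cell. The number is therefore not a frequency of these cells in the lymph node. Together the libraries held 27765 barcodes, of which 52 sequences occurred in both (exact Poisson 95% interval 38.8 to 68.2). These were 0.404% of the DTR-negative and 0.349% of the DTR-positive barcodes. The pool of barcodes reconstructed from the lists held 3679682 sequences, for which chance gives 52.1 shared barcodes, inside that interval. No barcode lay 1 base from another barcode of its own library. Pairs 2 bases apart numbered 922 of the 82670511 pairs within the DTR-negative library and 1319 of the 111086965 within the DTR-positive library. Between the libraries, 2293 of 191676254 pairs were 2 bases apart. The rate within over between was 0.93 (exact 95% interval 0.86 to 1.01) for the DTR-negative and 0.99 (0.93 to 1.06) for the DTR-positive library.

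Both libraries came with the same list of 33698 features, identical in content and order. Of these, 33696 were mouse genes with Ensembl identifiers, and the other 2 were the added sequences gfp and tdTomato, on the last rows. tdTomato is a red fluorescent protein, and gfp is the green fluorescent protein commonly used as a reporter. No feature was named for DTR, for HBEGF in capitals (the human gene whose product is the diphtheria toxin receptor) or for EGFP. The mouse gene Hbegf (ENSMUSG00000024486), which encodes the heparin-binding EGF-like growth factor, was on the list, at 36504927 to 36515805 on the minus strand of chromosome 18 in GRCm38. The list therefore has no separate row under those names for a receptor transgene that would check the labels. What gfp marks is not given in the sources used here, so whether its row could serve for that is open. All features were of the gene expression type, so no surface-protein tags were listed.

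Aire (ENSMUSG00000000731) was on the list. It lies on the minus strand of chromosome 10, from 78030022 to 78043610 in GRCm38. Its span overlaps Dnmt3l on the opposite strand, but none of the listed genes matched to M21 on its own strand. All 77 genes of the 14 marker lists were on the feature list under their exact symbols, and presence on the list says nothing of expression. The list for Aire-expressing and migratory dendritic cells had all 9 members, including Ccr7, the chemokine receptor that guides dendritic cells to lymph nodes, Fscn1, an actin-bundling protein, and the chemokine Ccl22. Ccr7 lies on the minus strand of chromosome 11 from 99144196 to 99155077. The antigen presentation list had all 7 members, including Ciita, the master regulator of MHC class II transcription, Cd74, the invariant chain, and H2-Ab1, an MHC class II chain on the plus strand of chromosome 17 from 34257689 to 34269419. The remaining lists were likewise complete. They included conventional dendritic cells of types 1 and 2, plasmacytoid dendritic cells, B, plasma, T and natural killer cells, macrophages and monocytes, neutrophils, lymph node stroma and cycling cells.

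Of the 78 mouse genes examined, the marker list members and Hbegf, 4 overlap another listed gene matched to M21 on the same strand. The 1684 listed genes absent from M21 had no coordinates here, so overlaps with them could not be found. Gene spans in the annotation used for counting may differ from those of M21. The overlap was taken over whole gene spans, introns included. Whether their exons overlap was not tested. Whether reads in introns were counted is not given in the sources used here, so it stays open which reads there can be told apart. Il4i1, an amino acid oxidase of mature dendritic cells, overlaps Nup62. Clec9a, a marker of type 1 conventional dendritic cells, overlaps Clec1b and Gm43914. Foxp3, the transcription factor of regulatory T cells, overlaps Flicr, and Ccr9, a gut-homing chemokine receptor, overlaps Gm17200. A further comparison found 17 of the 78 genes overlapping a matched gene on the opposite strand, among them Aire, Ciita and H2-Eb1, 1 of the MHC class II chains. Whether the counting used strand is not given in the sources used here.

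Of the 33696 mouse identifiers, 32012 (95.002%) were present in the M21 annotation and 1684 (4.998%) were absent. Every absent identifier had a number above the highest in M21. The matched features comprised 21409 protein-coding genes, 9803 long noncoding RNA genes, 427 immunoglobulin segments, 270 T cell receptor segments and 103 others. Immunoglobulin and T cell receptor segments thus had rows of their own, although reads from near-identical segments may be split or lost in counting. The 13 mitochondrial features were all protein coding, so mitochondrial ribosomal RNA was not among the matched features. Of the matched genes, 2635 carried another symbol than in M21. In the list as a whole, 26 symbols stood on more than 1 row, covering 52 rows, and 250 rows carried the identifier in place of a symbol.

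The order of the matched genes followed GRCm38 closely on 20 of the 21 chromosomes compared, where no window of 51 genes ran in reverse. Those 20 chromosomes together held 32 steps back to a lower start. The lowest rho of any window on them was 0.9986, on chromosome 5. Chromosome 14 differed. Its first 152 listed genes spanned 16.3 Mb of GRCm38 (chromosome 14, 3030002 to 19282822) and ran in reverse, with a Spearman's rho across genes of -0.9999 and 135 steps back to a lower start. The first listed gene, Gm48099, starts at 19.3 Mb, and the last of the 152, Gm2888, at 3.03 Mb. The remaining 1301 matched genes of the chromosome ran forward.

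**Figure D1:**
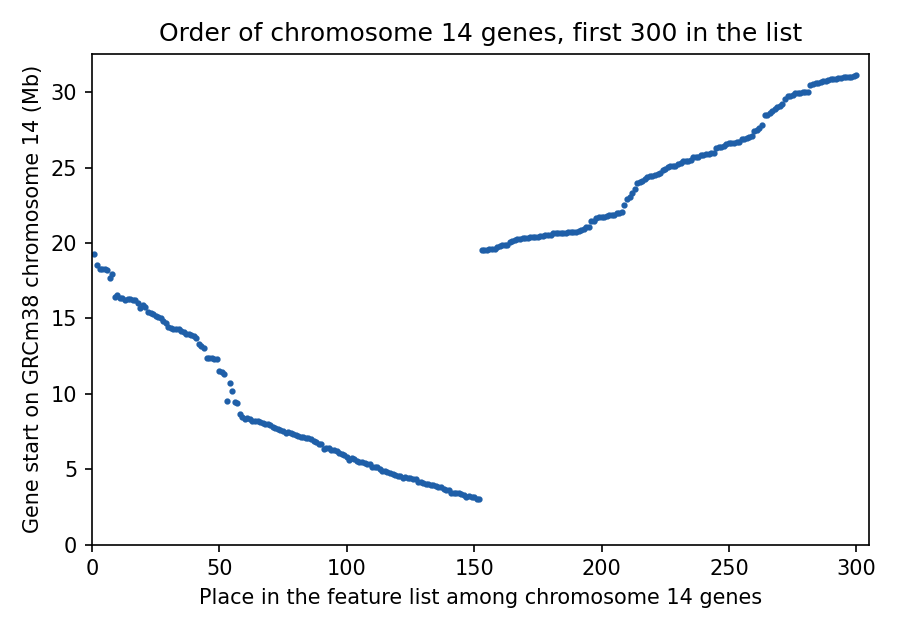
Start of each gene on GRCm38 chromosome 14 in Mb (vertical axis) against its place among the chromosome 14 genes of the feature list (horizontal axis), for the first 300 genes, 1 point per gene. The first 152 genes fall from 19.3 Mb towards the start of the chromosome, and the genes after them rise.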

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

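The alternatives were chosen before the data were examined, except the chance number recomputed from the words of each library alone. The numbers of barcodes per library could not move when the suffix was dropped, since every barcode carried the same one. The number shared was 46 when the longer list was cut at random to the length of the shorter, inside the counting interval of the uncut lists. Such a cut cannot raise the number and lowers it roughly with the list length, so this says little of stability. The chance number was 55.6 from the words of the DTR-negative library alone and 54.1 from those of the DTR-positive library alone. Both were inside that counting interval. The words of 1 library are part of those of both, so the chance number could only stay or rise. Its rise therefore says little of stability. Counting pairs 2 bases apart in place of 1 raised the pairs from 0 to 922 in the DTR-negative and from 0 to 1319 in the DTR-positive library. Words of the same linker differ by at least 2 bases, as do the linkers, so a count at 1 base could only be 0, and allowing 1 mismatch could only leave the shared number at 52. Neither says anything of stability. Counting features by symbol gave 33672. Matching marker symbols without regard to case could only give the same 77 genes, since all of them had matched exactly. The alternatives planned for expression per cell class (another cell filter, another clustering resolution and another scaling) were not run, since molecule counts were not analysed here. No paired analysis was possible because each group had 1 library, which also rules out leaving out a replicate. Depth per cell was not analysed here. The counting intervals limit only the barcode numbers.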

Other observations

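The tests of the shared barcodes and of the gene order were chosen after those results were seen, and the tests of close barcode pairs and of the identifiers before. No pattern below was tested against a biological explanation.

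The order of the feature list departs from the build named in the submitters' processing notes. Those notes name mm10, which is GRCm38. A list following that assembly would hold no long reversed run, yet sliding windows placed 112 genes of chromosome 14 in 1 such run, and none on the other 20 chromosomes. This number is below the 152 genes of the whole reversed stretch, because windows cannot be centred on the first genes of the list and those near the other end of the stretch also take in forward genes. M21 as the source of the list is also argued against, since 4.998% of the list's identifiers are absent from M21, above the limit of 1% set beforehand. A candidate explanation is that reads were counted against a later assembly in which the start of chromosome 14 is turned round. A later annotation on GRCm38 would bring later identifiers but not the reversed run. No later assembly was used here, so this stays a hypothesis, and coordinates joined to these features by mm10 position would need checking.

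The barcodes have a regular build. Bases 8 and 9 took only 4 of the 16 possible pairs, and no first or last word of 7 bases was seen with more than 1 of them. Each pair of bases came with 958 to 960 first words and as many last words, which gives the pool of 3679682 barcodes. The number of shared barcodes implies, without use of that structure, a pool of 3686082 (95% interval 2810870 to 4935519). That holds only if no shared barcode was carried over between the libraries. It restates the comparison of the shared number with the chance number, so it adds no separate support. From general knowledge of these kits, a pool of this size and build resembles the barcode list of a later 10x 3′ chemistry more than that of the version 3 named in the labels. The kit version is therefore in doubt. It was not tested, because neither barcode list was used here.

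Carry-over of reads between the libraries was weighed as a source of the 52 shared barcodes. With the pool taken from the words seen, chance alone gives 52.1. The interval then leaves room for at most 16.1 shared barcodes beyond it. This bears only on barcodes kept as cells in both lists, not on weaker carry-over. Cells split over close barcodes would raise the number kept per library. At 1 base apart the count was 0 in both libraries, which decides nothing because the pool holds no such pairs. At 2 bases apart, pairs within the DTR-negative library were 0.93 times as frequent as between the libraries (95% interval 0.86 to 1.01), and within the DTR-positive library 0.99 times (0.93 to 1.06), so no excess from splitting was seen. These intervals leave room for up to 6.70 and 83.1 pairs beyond the rate between the libraries. A small number of cells split over barcodes 2 bases apart is therefore not excluded. Cells split over barcodes further apart would not be seen by this comparison, so it says nothing of their number.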
